A study of Mus musculus with 6 samples.

How the data were processed

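RNA of ascending aorta, the first stretch of the vessel that leaves the heart, was measured on Agilent one-colour arrays of 60-base probes. Per the labels, each of the 6 arrays held tissue of a different mouse, 3 wild type and 3 with both copies of the low-density lipoprotein receptor gene Ldlr mutated, so the replicates were separate animals. Replicates were numbered in accession order, which pairs no arrays. The number of arrays limits the precision, and with 3 animals against 3 an exact two-sided permutation test cannot give a p below 0.1. Age, diet, time of collection and the part of Ldlr that was disrupted were not given in the sources used here.

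Per the file headers, the spots were read with Agilent Feature Extraction 12.0.3.1, which subtracted a fitted background surface and corrected spatial trends, and the processed intensity of each spot was deposited on a linear scale with no scaling between arrays. Mean spot intensity and median local background intensity were deposited beside it, together with other columns of flags per spot, per the file headers. A deposited table holds the authors' normalized log2 values for 56605 probes, made with limma per the submitters' processing notes, with no version or method given. Each column of that table correlated best with the scanner values of its own array (r of at least 0.99969, against at most 0.9879 with any other array). The slopes were 1.062, 1.032 and 1.012 for wild type and 0.9925, 0.969 and 0.966 for mutant, so all wild-type slopes lay above all mutant slopes. Column medians were 4.713, 4.718 and 4.726 for wild type and 4.729, 4.732 and 4.727 for mutant. Scale and direction are therefore those of log2 signal; the method that made the columns alike stays unknown.

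Each array had 62976 spots, of which 3671 were controls and were left out, as were spots that the scanner software marked as non-uniform or population outliers, between 110 and 159 per array. No probe was saturated. The spots of 300 probes that were printed 10 times were averaged. Log2 processed intensity was scaled by subtracting the 75th percentile of each array. A probe was kept where it was well above background on every array of at least 1 group, which left 32075 probes. Probe names were brought up to date through RefSeq accessions of the mouse reference table (assembly GRCm38.p6, used for names only): 32994 probes matched and 23611 kept the name in the files. For a gene with several probes the brightest over all 6 arrays was used, without regard to group, which gave 20998 genes, 6576 of them under a clone, locus or predicted name. Probe positions are those in the array files, on mouse build mm9.

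Mutant and wild-type arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and p-values were adjusted by the Benjamini-Hochberg method over all genes with a threshold of 0.05. All adjusted p-values for genes are from this test. Differences are log2 values of mutant minus wild type with their standard error (SE), n = 3 against 3. A second count took genes with an unadjusted p under 0.05 and a change of at least 2-fold. Where a probe was well above background on no array of a group, the difference is given as "at least N-fold": the mean of the brighter group against the mean, per array of the dimmer group, of the probe's own signal or the lowest signal of any probe well above background, whichever was higher. Where it was so on some arrays of a group, the log2 difference is given with the number of those arrays. A list median with members at their bound is given where it differs from the plain median.

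Before the data were examined, 36 gene lists were fixed, covering cell types of the wall and of blood, thymus, fat, heart, muscle and nerve, and lipid, inflammation, apoptosis, matrix, stress and clock genes. They hold 751 genes, of which 676 were measured. The 35 lists with at least 5 measured members were tested with limma's camera (preset correlation 0.01), which compares a list with all other genes, and adjusted over the lists. No list passed 0.05 when the correlation between genes was estimated from the arrays; the lowest adjusted p was then 0.211, and 7 lists had an unadjusted p under 0.05. Limma's fry, which asks only whether the genes of a list move on balance in a single direction, called 27 lists. The mean of a list per array was compared by exact permutation, and the groups were separated for 27 of 35 lists, each at the lowest possible p of 0.1.

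The genes named were chosen by a rule also fixed before the data were examined: Ldlr, the 12 largest rises and 12 largest falls among genes with a symbol that passed the threshold and whose groups did not overlap, the 4 members of each list with the smallest p, and 13 genes of atherosclerosis and apoptosis always given. Other genes are said to be chosen after their values were seen. Of the 162 genes, 64 had several probes, and for 5 of them (Pole2, Mbp, Lpl, Hmgcr and Casp3) a probe moved the opposite way. Genes near Ldlr were compared with all others by a two-sided Fisher's exact test.

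All 6 arrays shared 1 scan date and had different slide positions, so they may share 1 slide, but the slide number was not established here. Time of collection is not given, and dates of RNA extraction and labelling were not compared, so a batch from these steps cannot be excluded. Wild-type arrays and mutant 3 had positions in slide row 1 and mutants 1 and 2 in slide row 2. Alternatives tried were normexp background correction (offset 50) of mean spot and local background intensity, quantile and median scaling, other filters on dim probes, the mean of all probes, other variance settings, array weights, the deposited table, the slide row as a block or row 1 alone, and leaving out each array. Scaling to the spike-in control probes was added after the data were seen. The fit was tested on simulated arrays with the means and spread of the 20998 genes and with 67, 67 and 66 genes changed by 0.5, 1 and 2 on the log2 scale. It recovered 2.99%, 43.3% and 89.4% of them, and 9.09% of its 99 calls were unchanged genes. Far fewer genes changed in the simulation than the 10452 called in the data. The adjusted threshold depends on that number, so these shares recovered do not carry over to the real comparison. In a second simulation a list shifted by 1 on the log2 scale was called and no other list was. Its genes were drawn independently, so it cannot show how camera behaves where the genes of a list vary together. The data.table package (version 1.17.8) read the files, array weights used statmod 1.5.0, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.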

Results

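Gene expression in the ascending aorta was compared between 3 mice homozygous for a mutated Ldlr and 3 wild-type mice. Ldlr encodes the receptor that clears low-density lipoprotein from blood, and mice without it are a standard model of atherosclerosis. The series title names inflammation and apoptosis as its subject. Between 54.2% and 55.9% of probes were well above background on the wild-type arrays and between 58.5% and 58.7% on the mutant arrays.

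The mutant arrays were brighter. The 75th percentile of processed signal was 165, 182.6 and 216 on the wild-type arrays and 281.9, 314.6 and 284.1 on the mutant arrays. Spike-in control probes receive RNA added in the labelling, and those not well above background throughout were left out. Of the probes used, some were slightly brighter on the mutant arrays (by 0.03 and 0.06, log2) and the rest dimmer. Their mean was slightly lower on the mutant arrays (11.53 ± 0.05 against 11.68 ± 0.04, log2, SD, n = 3). The gene signal relative to the spike-in probes was therefore 0.80 higher on the log2 scale in the mutant, and all 3 mutant arrays lay above all 3 wild-type arrays (exact permutation p = 0.1, the lowest possible). All values below are relative to the 75th percentile of each array.

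**Figure D1:**
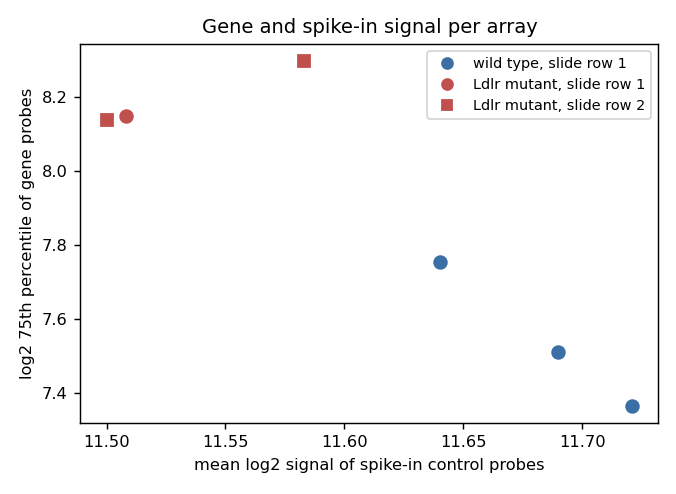
Log2 75th percentile of gene probe signal (vertical axis) against the mean log2 signal of spike-in control probes (horizontal axis), 1 point per array, with squares for the second slide row. Mutant arrays lie above wild-type arrays in gene signal and to their left in spike-in signal, a difference of 0.65 and of -0.15 on the log2 scale.

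The first comparison was of the targeted gene itself. Ldlr fell by 4.78 ± 0.17 (SE) on the log2 scale at its brightest probe (chromosome 9, 21554277 to 21554336, mm9), which left 3.65% of the wild-type signal (adjusted p = 3e-05). The normalized log2 level was 2.92 ± 0.27 (SD, n = 3) in wild type and -1.86 ± 0.19 in the mutant, and the 3 mutant arrays, at -1.80, -1.71 and -2.07, were still well above background. Of the other probes on the gene, that at 21545138 fell by 2.83 ± 0.28 and that at 21542791 by 1.54 ± 0.17 (adjusted p over all probes 0.000494 and 0.00083). The probe at 21552792 had a wild-type mean of -1.42 ± 0.11. It lay within the wild-type range on mutant 3 (-1.43), slightly below it on mutant 2 (-1.65) and at -6.31 on mutant 1. The difference of -1.72 ± 1.26 did not pass (adjusted p = 0.29). Which of these probes lie in the disrupted part is not given in the sources used here.

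**Figure D2:**
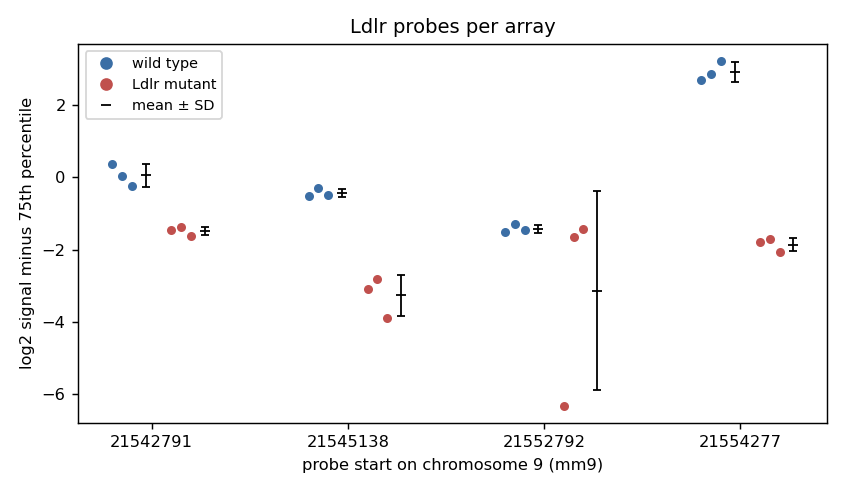
Normalized log2 signal (vertical axis, relative to the 75th percentile of the array) of the 4 Ldlr probes, ordered by start position on chromosome 9 of mm9 (horizontal axis). Points are arrays, 3 per genotype, and bars the mean ± SD; at 21554277 the mutant arrays lie between -2.07 and -1.71 and the wild-type arrays between 2.69 and 3.22.

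Across the transcriptome the genotypes differed broadly. Of 20998 genes, 10452 changed, 4718 higher and 5734 lower in the mutant. Among the 14422 with a gene symbol 3887 were higher and 3513 lower, while among the 6576 with only a clone, locus or predicted name 831 were higher and 2221 lower. The lowest scaled log2 signal of any probe well above background was -3.721, -3.957 and -3.97 on the wild-type arrays. It was -4.297, -4.465 and -4.493 on the mutant arrays, so signals near background can lie lower there through the scaling. Its share in the falls of dim genes was not tested. At least 2-fold changes at an unadjusted p under 0.05 were found for 2307 genes higher and 1636 lower, against 1355 and 558 with normexp background correction, 7031 and 260 with spike-in scaling, and 1428 higher with probes well above background on all 6 arrays. Without a filter on dim probes 3072 were lower. The groups did not overlap for 62.2% of genes, where chance gives 10%. Of the higher genes 611 were not well above background on any wild-type array, and of the lower genes 91 were not so on any mutant array. The balance of directions depended on the scaling: 45.1% of calls were higher with the 75th percentile, and 95% (13354 higher, 708 lower) with spike-in scaling, which moved the median difference of all genes from -0.06 to 0.75. Without a filter on dim probes it was 30.7%. With the slide row as a block 8165 genes changed, and within row 1 alone, which holds all wild-type arrays and mutant 3, 6813 genes did (3101 higher, 3712 lower). Row 2 holds mutant arrays only, so both values rest on mutant 3 as the sole array against wild type and are not separate checks.

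Arrays of a genotype resembled each other more than those of the other genotype. Pearson correlations over genes were 0.9863 to 0.9881 within wild type, 0.9865 to 0.9896 within the mutant and 0.9005 to 0.9343 between them, and the first principal component, which parted the genotypes, held 82.5% of the variance. Genes are not independent replicates, so these values describe the arrays and test nothing.

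The 12 largest rises included Itgax and Mpeg1 of the macrophage list, members of other lists and genes on none. Spp1, which encodes the secreted matrix protein osteopontin, rose 1989-fold (10.96 ± 0.10, SE, adjusted p = 2.96e-07). Cd5l, a secreted protein of tissue macrophages, rose by 9.94 ± 0.34, and Mpeg1, which encodes a pore-forming protein of phagocytes, by 7.87 ± 0.23. The integrin Itgax was not well above background in wild type and rose at least 333-fold. By the same measure Atp6v0d2, a proton pump subunit, rose at least 159.5-fold, the transporter Slc15a3 at least 83.8-fold, Bex1 at least 83.6-fold and the acute-phase protein Saa3 at least 81.1-fold. The fungal receptor Clec7a (8.51 ± 0.33) and the survival gene Bcl2a1d (7.99 ± 0.53) were measured on 2 of 3 wild-type arrays, and the elastase Mmp12 (8.50 ± 0.71) and the cytokine receptor Il7r (8.22 ± 0.33) on 1 of 3, so their rises rest on wild-type signals near the floor.

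Among the 12 largest falls were Ldlr and 4 genes of the clock list. The clock output factor Dbp fell by 4.74 ± 0.31, and the clock genes Nr1d1 and Per3 by 3.19 ± 0.49 and 3.13 ± 0.12. The clock repressor Ciart was not well above background in the mutant and fell at least 7.77-fold. Tcap, which encodes a protein of the muscle Z-disc, fell by 4.58 ± 0.22. Rfx2, a transcription factor, fell by 3.29 ± 0.25, and Lypd6b by 3.40 ± 0.42. Rhox3a, Olfr1338 and Vgll2 were not well above background in the mutant and fell at least 10.8-, 5.82- and 2.99-fold. Pole2, a DNA polymerase subunit, fell by 3.59 ± 1.08 at its brightest probe, measured on 2 of 3 mutant arrays (adjusted p = 0.0326), and its other probe moved the opposite way.

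Of the 35 gene lists tested, 20 were higher and 2 lower than other genes. None of these calls was kept with an estimated correlation between genes. List medians depend on the handling of dim probes. With normexp background correction they were 2.82 for adhesion molecules and chemokines, 1.89 for class II presentation, 1.12 for cell division, 0.81 for interferon-stimulated genes, 0.88 for lipid uptake, 0.76 for cartilage and bone genes, 0.54 for neutrophil genes and 0.45 for T cell genes, all still called higher. Without a filter the medians of red cell and neutrophil genes were 1.27 and 0.71, and with the mean of all probes that of structural matrix genes was 0.15. With spike-in scaling every list median lay 0.80 higher.

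**Figure D3:**
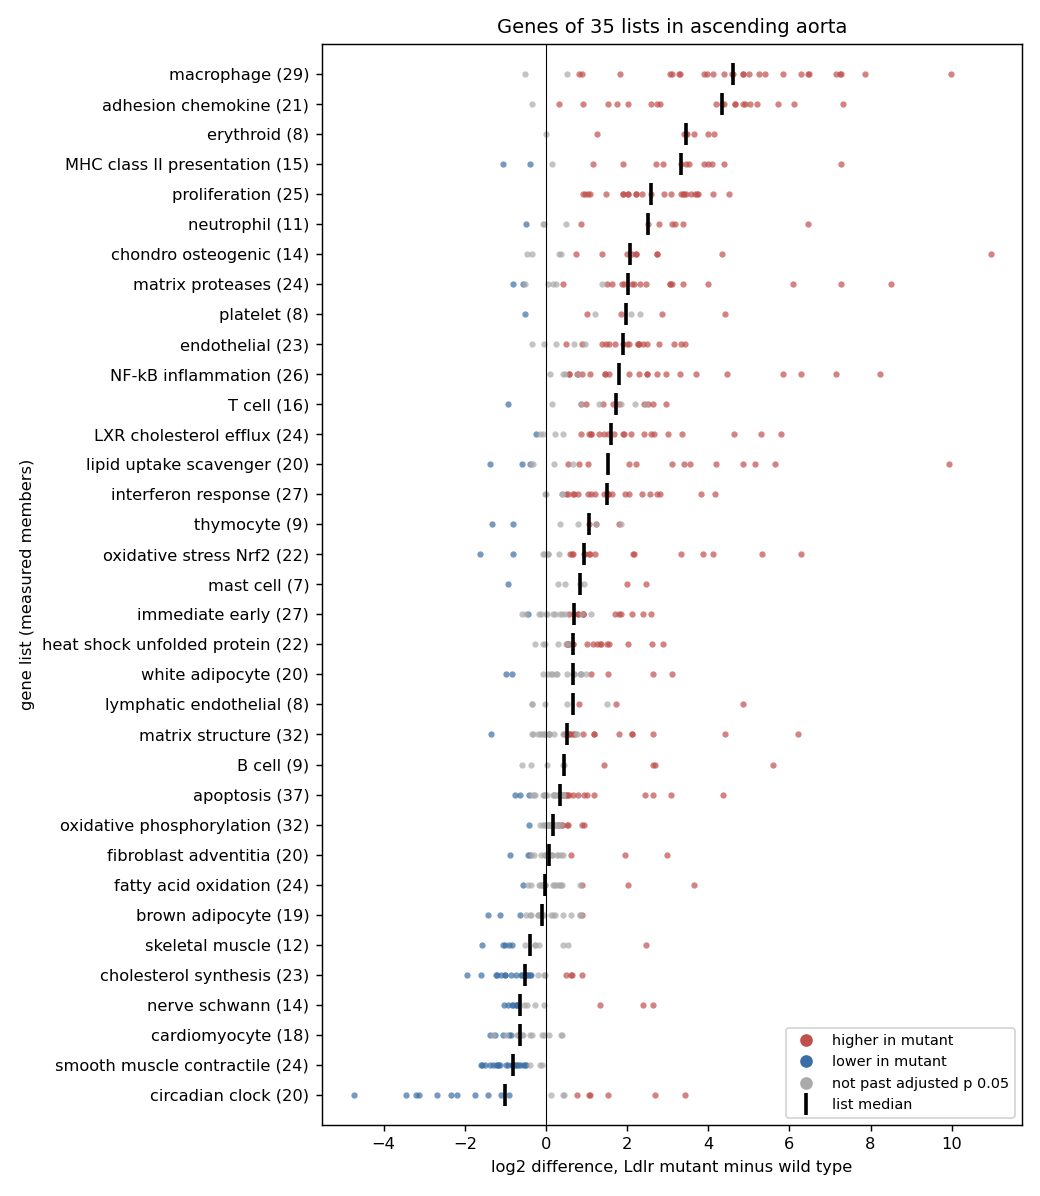
Log2 difference, mutant minus wild type (horizontal axis), of each measured gene in 35 lists (vertical axis, with the number of measured genes), with black bars at the list medians. Points are coloured by whether the gene was higher, lower or not past an adjusted p of 0.05; the medians run from -1.01 for clock genes, whose members lie on both sides, to 4.61 for macrophage genes. With spike-in scaling the medians of the contractile, cardiomyocyte, nerve, skeletal muscle, cholesterol synthesis, brown adipocyte and fatty acid oxidation lists move to between -0.02 and 0.78.

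Macrophage genes rose together. Of 29 measured members 27 were higher and none lower (28 when adjusted over the list alone), with a median difference of 4.61 (camera adjusted p = 4.21e-16; adjusted p = 0.211 with an estimated correlation). Trem2, a lipid-sensing receptor, rose by 7.25 ± 0.21, the membrane protein Ms4a7 by 6.48 ± 0.19 and the lysosomal marker Cd68 by 6.45 ± 0.27. Genes of antigen presentation on class II molecules followed, with 12 of 15 higher and 2 lower (the same counts adjusted over the list alone) and a median of 3.34 (adjusted p = 4.52e-06; adjusted p = 0.211 with an estimated correlation). Among them H2-Ab1 rose 15.96-fold, H2-Eb1 by 3.52 ± 0.18 and the cathepsin Ctss by 7.27 ± 0.23.

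Inflammatory and adhesion genes were also higher. Adhesion molecules and chemokines rose for 20 of 21 members (20 adjusted over the list alone), with a median of 4.34, or 3.61 with members at their bound (adjusted p = 2.99e-11; adjusted p = 0.211 with an estimated correlation). The leukocyte adhesion molecule Vcam1 rose by 4.39 ± 0.15, the monocyte chemokine Ccl2 by 6.11 ± 0.21, and Ccl4 and the endothelial selectin Sele, both not well above background in wild type, at least 36.1-fold and 5.12-fold. NF-kB targets rose for 22 of 26 members (23 adjusted over the list alone), with a median of 1.79, or 1.45 with members at their bound (adjusted p = 4.1e-11; adjusted p = 0.212 with an estimated correlation), among them Il6 at least 19.6-fold, Il1rn at least 31.0-fold, Il1b at least 8.27-fold and the feedback inhibitor Tnfaip3 by 2.50 ± 0.14. Interferon-stimulated genes rose for 23 of 27 (24 adjusted over the list alone), with a median of 1.49, or 1.43 with members at their bound (adjusted p = 3.42e-09; adjusted p = 0.212 with an estimated correlation), including Oas1a by 4.16 ± 0.25 and Irf7 by 1.49 ± 0.10.

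Genes of lipid handling moved in different directions. Targets of liver X receptors and cholesterol efflux genes rose for 19 of 24 members and fell for 1 (the same counts adjusted over the list alone), with a median of 1.60 (adjusted p = 3.62e-08; adjusted p = 0.211 with an estimated correlation). The cholesterol exporters Abcg1 and Abca1 rose by 5.80 ± 0.23 and 3.34 ± 0.16, the apolipoprotein Apoe by 3.02 ± 0.14 and the lysosomal sterol carrier Npc2 by 2.10 ± 0.13. Lipid uptake and scavenger genes rose for 13 of 20 and fell for 3 (the same counts adjusted over the list alone), with a median of 1.54, or 1.37 with members at their bound (adjusted p = 0.000227; adjusted p = 0.211 with an estimated correlation), and Fabp5, a fatty acid carrier, rose by 5.64 ± 0.24. Cholesterol synthesis genes fell for 16 of 23 and rose for 4 (the same counts adjusted over the list alone), with a median of -0.51, which turned to 0.29 with spike-in scaling, when 7 were higher and 2 lower. The list lay below other genes (camera adjusted p = 0.00586, and 0.212 with an estimated correlation). With spike-in scaling, which moves every gene by the same amount, the list median had to stay below that of all genes. Camera also depends on the spread between arrays, so its adjusted p of 0.00402 was not fixed by the offset. It rests on the same arrays. Dhcr24 fell by 1.94 ± 0.19, Sqle by 1.60 ± 0.12, Stard4 by 1.22 ± 0.10 and Fdft1 by 1.21 ± 0.13, while Hmgcr, the rate-limiting enzyme, rose by 0.62 ± 0.16 at its brightest probe with the other probe moving the opposite way.

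Apoptosis genes changed in part. Of 37 members 18 were higher, 3 lower and 16 not past the test (19 and 4 when adjusted over the list alone), with a median of 0.35 (adjusted p = 0.000802; adjusted p = 0.211 with an estimated correlation). The pro-apoptotic genes Bid and Bcl2l11 rose by 2.45 ± 0.11 and 2.63 ± 0.15, and Pmaip1, not well above background in wild type, at least 12.4-fold. Birc5, an inhibitor of apoptosis that is also expressed in dividing cells, rose by 3.09 ± 0.15. The effector caspase Casp3 rose by 1.02 ± 0.18 at its brightest probe, measured on 2 of 3 wild-type arrays, but its other probe moved the opposite way, and the rise was lost with probes well above background on all 6 arrays (-0.28, adjusted p = 0.36). Bcl2, which protects against apoptosis, fell by 0.42 ± 0.14 (adjusted p = 0.0432), a difference that turned to 0.39 with spike-in scaling. Bax, a pore-forming effector, differed by 0.20 ± 0.13 and did not pass (adjusted p = 0.238).

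Cell division genes rose throughout the list. All 25 members were higher (25 adjusted over the list alone), with a median of 2.60, or 2.03 with members that were not well above background in wild type at their bound (adjusted p = 8.02e-15; adjusted p = 0.211 with an estimated correlation). The mitotic kinase Plk1 rose by 2.03 ± 0.09, and Aurkb, Ccnb1 and Cdk1, not well above background in wild type, at least 2.96-, 8.23- and 3.33-fold. Heat shock and unfolded protein genes rose for 16 of 22 (18 adjusted over the list alone), with a median of 0.68 (adjusted p = 1.7e-05; adjusted p = 0.348 with an estimated correlation), such as the chaperones Hspa5 by 1.16 ± 0.16 and Sdf2l1 by 2.90 ± 0.29. Oxidative stress genes rose for 15 of 22 and fell for 2 (16 and 2 adjusted over the list alone), with a median of 0.94 (adjusted p = 6.95e-05; adjusted p = 0.211 with an estimated correlation). The phagocyte oxidase subunits Ncf4, Ncf2 and Ncf1 rose by 5.32 ± 0.25, 4.13 ± 0.26 and 3.34 ± 0.15, the last measured on 2 of 3 wild-type arrays, and Nox4, the oxidase of smooth muscle, fell by 1.62 ± 0.12. Immediate early genes rose for 13 of 27 and fell for 1 (14 and 1 adjusted over the list alone), with a median of 0.68 (adjusted p = 0.00102; adjusted p = 0.218 with an estimated correlation), including Myc by 2.58 ± 0.21 and Atf3 by 1.85 ± 0.23. Oxidative phosphorylation genes differed little: 8 of 32 were higher and 1 lower (5 and 1 adjusted over the list alone), with a median of 0.18 (adjusted p = 0.0116; adjusted p = 0.568 with an estimated correlation). That call ended with quantile normalization (camera adjusted p = 0.0713), with the deposited table (0.196) and without mutant replicate 1 (0.07), and fry did not make it (adjusted p = 0.0653). With the slide row as a block and in row 1 alone, which rest on mutant 3, the median was 0.097. Cox5a rose by 0.89 ± 0.13.

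In the vessel wall, contractile genes of smooth muscle and endothelial genes moved apart. Of 24 contractile members 21 were lower and none higher (21 adjusted over the list alone), with a median of -0.82 (camera adjusted p = 4.35e-07, and 0.256 with an estimated correlation). With spike-in scaling the median was -0.02, with 4 lower and 2 higher. That scaling moves every gene by the same amount, so the list median had to stay below that of all genes, which is no separate result. Camera also depends on the spread between arrays, so its adjusted p of 1.5e-08 was not fixed by the offset. It rests on the same arrays. The myosin heavy chain Myh11 fell by 1.56 ± 0.09, smoothelin (Smtn) 2.82-fold, Ppp1r14a by 1.37 ± 0.10, Tpm1 by 1.19 ± 0.10 and calponin (Cnn1) by 0.93 ± 0.10. The actin Acta2 fell by 0.69 ± 0.17, a difference that turned to 0.12 with spike-in scaling. Endothelial genes rose for 18 of 23 (20 adjusted over the list alone), with a median of 1.89 (adjusted p = 3.5e-08; adjusted p = 0.212 with an estimated correlation), among them Emcn by 3.15 ± 0.20, Sox18 by 3.32 ± 0.28, Plvap by 2.38 ± 0.19 and Pecam1 by 1.54 ± 0.13. Of 20 markers of adventitial fibroblasts 3 were higher and 3 lower (3 and 1 adjusted over the list alone), with a median of 0.08 (camera adjusted p = 0.385). When single arrays were left out the median ran from -0.13 without wild-type replicate 1 to 0.25 without wild-type replicate 3, and it was 0.31 in slide row 1. The list was called higher without a filter on dim probes (camera adjusted p = 0.0422). Lum rose by 2.99 ± 0.21 and Cygb fell by 0.90 ± 0.14.

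Matrix genes rose selectively. Structural matrix genes were higher for 16 of 32 members and lower for 1 (the same counts adjusted over the list alone), with a median of 0.53 (adjusted p = 0.000601; adjusted p = 0.367 with an estimated correlation). Thbs1 rose by 6.23 ± 0.36, Col8a1 by 4.42 ± 0.21, Col12a1 by 2.63 ± 0.26 and the crosslinking enzyme Lox by 2.12 ± 0.22. Proteases and their inhibitors rose for 17 of 24 and fell for 2 (18 and 3 adjusted over the list alone), with a median of 2.03 (adjusted p = 9.57e-08; adjusted p = 0.211 with an estimated correlation), including the inhibitor Timp1 16.04-fold, Adamts4 by 2.32 ± 0.10 and the collagenase Mmp13 at least 18.5-fold. Cartilage and bone genes, to which Spp1 belongs, rose for 10 of 14 (10 adjusted over the list alone), with a median of 2.06, or 1.69 with members at their bound (adjusted p = 0.000563; adjusted p = 0.28 with an estimated correlation), and the cartilage collagen Col2a1 rose by 2.23 ± 0.30.

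Markers of blood cells were also higher in the mutant. Red cell genes rose for 7 of 8 members (7 adjusted over the list alone), with a median of 3.45 (adjusted p = 0.00124; adjusted p = 0.34 with an estimated correlation), such as the globin Hbb-b2 by 4.13 ± 0.54 and the haem synthesis enzyme Alas2 by 3.64 ± 0.55, the latter measured on 2 of 3 wild-type arrays. Neutrophil genes rose for 7 of 11 and fell for 1 (the same counts adjusted over the list alone), with a median of 2.51, or 1.04 with members at their bound (adjusted p = 0.00541, and 0.212 with an estimated correlation), Lcn2 by 6.46 ± 0.23 and Ly6g by 2.51 ± 0.13. Ngp, Retnlg, Cxcr2, Fpr1 and Stfa2l1 of the neutrophil list were on the array, but no probe of theirs was kept. T cell genes rose for 9 of 16 and fell for 1 (14 and 1 adjusted over the list alone), with a median of 1.72 (adjusted p = 0.00235; adjusted p = 0.386 with an estimated correlation), and the call ended when only probes well above background on all 6 arrays were kept (median 0.98, adjusted p = 0.0528). The co-stimulatory receptor Cd28 rose by 1.42 ± 0.30, while Cd247 fell by 0.93 ± 0.12.

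The other cell type lists did not pass with the settings used throughout. Platelet genes had a median of 1.97 with 4 of 8 higher and 1 lower (adjusted p = 0.0548), Clec1b, measured on 2 of 3 wild-type arrays, rising by 4.41 ± 0.65. B cell genes had a median of 0.45 with 4 of 9 higher (adjusted p = 0.1), and Blnk, an adaptor of B cells and macrophages, rose by 5.60 ± 0.26. Mast cell genes had a median of 0.83 with 2 of 7 higher and 1 lower (adjusted p = 0.0838), lymphatic genes 0.66 with 3 of 8 higher (adjusted p = 0.159) and thymocyte genes 1.06 with 3 of 9 higher and 2 lower (adjusted p = 0.283). White fat genes had a median of 0.68 with 4 of 20 higher and 2 lower (adjusted p = 0.0704), brown fat genes -0.09 with 1 of 19 higher and 3 lower (adjusted p = 0.788) and fatty acid oxidation genes -0.02 with 3 of 24 higher and 1 lower (adjusted p = 0.228). Among these Cebpa of the white fat list rose by 2.63 ± 0.24 and the mitochondrial carrier Ucp3 by 3.66 ± 0.27. Plin4 and Slc2a4 of the white fat list were lower on every mutant array than on any wild-type array. The level of Plin4 was 6.43, 6.55 and 6.53 in wild type and 5.31, 5.74 and 5.53 in the mutant. The brown fat regulators Prdm16 and Ppargc1a fell by 1.43 ± 0.11 and 1.14 ± 0.20. Heart muscle genes had a median of -0.64 with 5 of 18 lower (adjusted p = 0.0838), skeletal muscle genes -0.40 with 5 of 12 lower and 1 higher (adjusted p = 0.181) and nerve genes -0.63 with 7 of 14 lower and 3 higher (adjusted p = 0.224). These 3 medians turned to 0.17, 0.40 and 0.18 with spike-in scaling. Of the 4 measured genes of the Y chromosome each was well above background on all 6 arrays, and Xist was so on 0 arrays.

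Most of these lists passed with some other setting, with the adjusted p, and the median where named, under that setting in brackets. The platelet list passed without a filter on dim probes (0.00229), with the mean of all probes (0.0299), with array weights (0.0276), and without wild-type replicate 1 (0.0466), 2 (0.0477) or 3 (0.0187) or mutant replicate 3 (0.0135), while its median was 0.94 in slide row 1. White fat genes passed in 8 settings (from 0.0011 without a filter to 0.049 with median scaling), among them without wild-type replicate 1 (0.00148, median 1.04) or mutant replicate 3 (0.0335), and had a median of 0.30 without wild-type replicate 3. Heart muscle genes were called lower than other genes with normexp (0.0372), with median scaling (0.0397), with spike-in scaling (3e-05), and without wild-type replicate 1 (0.0466) or 2 (0.0122, median -1.09). Their median was -0.22 without wild-type replicate 3. B cell genes passed with the mean of all probes (0.0062, median 2.60), without a filter (0.0288) and without mutant replicate 3 (0.0455), and had a median of 0.02 with probes well above background on all 6 arrays. Fatty acid oxidation genes passed with normexp (0.0168, median 0.18), without a filter (0.0116) and without mutant replicate 3 (0.0461, median 0.12), lymphatic genes without a filter (0.00818) and mast cell genes without wild-type replicate 2 (0.0194). By fry the B cell, mast cell and lymphatic lists were higher and the nerve and skeletal muscle lists lower (0.0019 to 0.0266). When single arrays were left out the brown fat median ran from -0.39 without mutant replicate 1 to 0.18 without mutant replicate 3. The median of skeletal muscle genes was -0.72 without wild-type replicate 2 (camera adjusted p = 0.0715).

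Clock genes changed in opposite directions. Of 20 members 11 were lower and 6 higher (the same counts adjusted over the list alone), with a median of -1.01, and camera did not call the list (adjusted p = 0.228), but did with spike-in scaling (median -0.20, adjusted p = 2.8e-06), as did fry (adjusted p = 0.00115), lower both times. Besides Dbp, Per3, Nr1d1 and Ciart, the output factors Tef and Hlf fell by 2.34 ± 0.18 and 2.69 ± 0.26, Nr1d2 by 2.18 ± 0.32 and Per2 by 1.75 ± 0.43. In contrast, Nfil3, which opposes Dbp at shared binding sites, rose by 3.43 ± 0.24, and Arntl, which drives the period genes, by 2.68 ± 0.33. Cry1, Npas2 and Clock differed by 0.46 ± 0.25, 0.42 ± 0.26 and 0.11 ± 0.13 and did not pass. Hlf, Nr1d2, Per2, Arntl, Bhlhe40, Cry1, Npas2 and Clock were named after their values were seen.

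**Figure D4:**
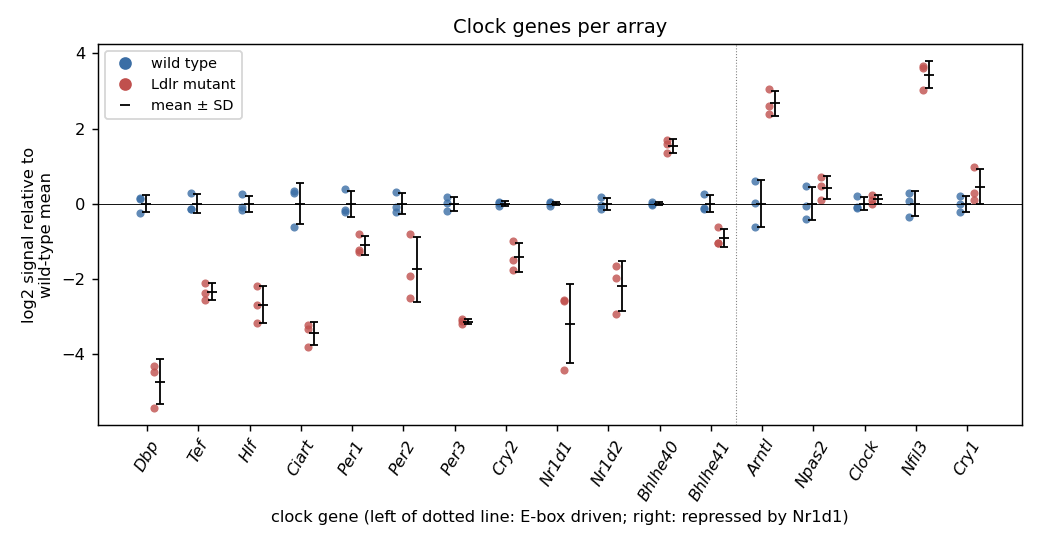
Log2 signal relative to the wild-type mean (vertical axis) of 17 clock genes (horizontal axis), with 3 wild-type and 3 mutant arrays as points and mean ± SD as bars. Left of the dotted line, Dbp lies lowest in the mutant and Bhlhe40 alone lies above wild type (1.54 ± 0.12, SE); to the right, Nfil3 and Arntl lie highest.

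Genes close to Ldlr were examined because a targeted allele can carry flanking sequence of another strain. Of 155 genes within 10 Mb of Ldlr on chromosome 9, 52.3% had an unadjusted p under 0.05, against 57.2% of 20757 other genes. The odds ratio was 0.82 (95% interval 0.59 to 1.14, Fisher's exact test, two-sided p = 0.223), so no excess of changed genes near Ldlr was found. The changed genes there included Icam1, an adhesion molecule (2.73 ± 0.22), and Acp5, an acid phosphatase of osteoclasts and macrophages (4.37 ± 0.30), both named after their values were seen. Neighbouring genes are not independent, so the test is descriptive.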

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

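Spike-in scaling was the only setting chosen after the data were seen. Ldlr stayed lower and past the threshold in every setting (-4.99 to -2.72), and without each array in turn between 8443 and 9513 genes changed. The odds ratio near Ldlr stayed below 1 with windows of 5 and 20 Mb and at the adjusted threshold, and passed only with 5 Mb and the adjusted threshold together (0.638, Fisher's exact p = 0.0331). Of 158 named genes that passed, 115 kept direction and call in every setting in which they were measured, and 148 kept their direction. No paired analysis was possible because replicate numbers only follow accession order.

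With normexp background correction 1913 genes passed 2-fold (1355 higher, 558 lower). With spike-in scaling 13354 genes were higher and 708 lower, 7291 passed 2-fold (7031 higher, 260 lower), and 4 lists were lower, the clock and cardiomyocyte lists being added; the whole distribution moves with this scaling. Without a filter on dim probes, which adds mostly dim genes, 9457 genes were lower, 3072 of the 2-fold genes were lower, and with probes well above background on all 6 arrays 1428 of the 2-fold genes were higher. In slide row 1 alone, with a single mutant array assumed to vary like the wild type, 6813 genes changed (3101 higher, 3712 lower). With an estimated correlation camera called 0 lists (0 higher, 0 lower), and fry called 5 lists lower. Signs turned with normexp for Spib (-0.0532) and Cd8a (-0.0277), with spike-in scaling for Acot11 (0.17), Hmgcs2 (0.25), Sox10 (0.0619), Sdhc (0.39), Itgb3 (0.30), Acta2 (0.12) and Bcl2 (0.39), and with probes well above background on all 6 arrays for Casp3 (-0.28); for the normexp and probe filter settings the cause was not tested. Signals near background limit the folds of genes dim in 1 genotype.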

Other observations

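All tests in this part were chosen after the result was seen, except the splits of the arrays. Gene families, taken as the 189 groups of at least 10 measured symbols with the same leading letters, were compared with all 14422 symbols, of which 27% were higher and 24.4% lower (Fisher's exact test, two-sided, adjusted over 378 tests). Zinc finger genes (Zfp) stood out: 187 of 359 were lower and 17 higher (adjusted p = 1.21e-27 for lower), with a median of -0.37. With spike-in scaling 6 were lower and 145 higher and their median was 0.44, so they then lay low only relative to all symbols, of which 68.7% were higher and 2.45% lower, with a median of 0.81. A-kinase anchoring genes (Akap) were lower for 8 of 12 (adjusted p = 0.0365) and ankyrin repeat genes (Ankrd) for 17 of 33 (adjusted p = 0.0164), and their medians of -0.49 and -0.29 likewise turned to 0.31 and 0.52 with spike-in scaling, when 3 Akap genes were higher and 1 lower, and 16 Ankrd genes higher and 1 lower. Among the rising families, C-type lectins (Clec) were higher for 15 of 20 (adjusted p = 0.000815), Toll-like receptors (Tlr) for 8 of 11 and the Ms4a group for 8 of 11 (adjusted p = 0.0332 for both). Clec4d rose at least 90.3-fold and Tlr8 at least 13.3-fold, and Ms4a6d rose by 6.65 ± 0.70, measured on 2 of 3 wild-type arrays. COMMD genes, which act in endosomal sorting, were higher for 9 of 10 by small amounts, with a median of 0.45 (adjusted p = 0.00178). With spike-in scaling 9 of 10 were again higher, with a median of 1.25, but most symbols were higher too, so the excess in number is smaller. Ribosomal protein genes (Rpl) changed less often than other symbols with scaling to the 75th percentile, 2 of 50 higher and 2 lower (adjusted p = 0.00178 and 0.00535) with a median of -0.01. With spike-in scaling 44 were higher and 0 lower, with a median of 0.79, close to that of all symbols.

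Clock genes changed in opposite directions. Genes driven through E-boxes had a median of -2.26 (12 genes, Bhlhe40 alone higher) and genes repressed by Nr1d1 a median of 0.46 (5 genes, of which Nfil3 and Arntl passed and Cry1, Npas2 and Clock did not), a difference of 2.72 (exact permutation p over genes 0.0326; genes are not independent replicates). Dilution of smooth muscle RNA by RNA of other cells as the only cause is argued against, since the first group differed from the contractile list by -1.44 (permutation p over genes 3e-05). The large falls of Dbp, Per3, Nr1d1 and Ciart, members of the first group, were known before this test was chosen, so its p adds little. With spike-in scaling, which moves every gene by the same amount and so cannot decide whether scaling adds to the pattern, the median of the first group was -1.46. A fall of the first group with a rise of Nfil3 and Arntl is consistent with collection of the genotypes at different times of day; an effect of the genotype on the clock is as open, since times of collection are not in the sources used here.

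Contractile genes were lower by a median difference of -0.82. With spike-in scaling the median was -0.0182, with 4 members lower and 2 higher in place of 21 and 0. Whether their own level fell or that of other genes rose therefore stays open, since the amount of tissue RNA labelled is not given in the sources used here. A lower share of smooth muscle cells as the only change is argued against, because markers of the other wall cells moved apart. The endothelial median lay 1.81 above the fibroblast median (permutation p over genes 5e-04, where genes are not independent replicates). It lay 1.45 to 1.91 above it over the settings tried, which reuse the same arrays. The median of 4.61 for macrophage genes, known before this test was chosen, already spoke against that explanation, so the test adds little. Lower expression of contractile genes within muscle cells of the mutant, or added RNA of incoming cells together with changes in other wall cells, stays open and was not tested.

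Red cell genes were higher by a median of 3.45. With spike-in scaling the median was 4.26, which follows from the shared offset and decides nothing. More blood left in the mutant samples is a candidate explanation, since platelet genes had a median of 1.97. An exact sign-flip test of the sum over the 8 genes gave p = 0.0156. These genes are not independent replicates, so that p does not measure the spread between mice. The list did not pass by fry (adjusted p = 0.0553) and passed camera only in some settings, and Itgb3, which wall cells also express, was lower. Bleeding into the wall of mutant vessels would give the same genes and stays open.

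The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. Only the real split, 1 of 10, gave as many changed genes (10452, highest other 6) and as many genes past 2-fold (3943, highest other 68). For the lists, 7 of the 10 splits gave at least the 22 called, and the highest other gave 24. Camera with its preset correlation called between 19 and 24 lists in these mixed groups. Each mixed split holds the genotypes in unequal numbers, so part of the genotype difference stays between its groups, for the same genes. The number of lists called therefore cannot decide whether the list calls exceed those of unrelated groups.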
